A study of Rattus norvegicus with 20 samples.

How the data were processed

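Liver RNA of male Wistar rats, an outbred laboratory strain, was measured on Affymetrix rat expression GeneChips. Per the labels' protocols, rats were put on a reduced diet at 6 weeks of age, with 5, 10, 20 or 30% restriction or none, for 1 week or 1 month, and were fasted for 16 h before the liver was taken. The sample labels give an age of 6 weeks for the 1 week arrays and of 9 weeks for the 1 month arrays, and do not say whether this is the age at the start or at sampling. Per the labels' protocols, the RNA of 5 rats was pooled for each group, 10 ug of it was labelled, and each of the 10 pools was run on 2 arrays, giving 20 arrays. The deposited values are intensity values on a linear scale, 1 per probe set, made with MAS5 per the submitters' processing notes; its version and its scaling target are not given in the sources used here.

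The deposited intensity values were not on a common scale. The 2% trimmed mean ran from 38.8 to 99.6 signal units over the 20 arrays, a 2.57-fold range, and both extremes were arrays of the 30% pool at 1 month. The design fixed before the data were examined had taken the signals as already scaled. Before any test was run, quantile normalization between arrays therefore became the reported setting, and the signals as deposited became an alternative. The 32 values of 0 were set to the smallest positive value of their array, signals were turned to log2, and 57 control probe sets were left out. Of the other 15866 probe sets, the upper 60% by mean log2 signal, 9520 probe sets, were tested. The lowest mean signal among them was 11.7 units (3.54 on the log2 scale). MAS5 detection calls were not used here. Where pools of a named gene lay under that level in a difference between groups, the fold is given as a lower bound, written as at least, from group means with pool values under it raised to it. For such genes in a dose trend the slope was fitted again with those values raised, which is no bound.

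Probe sets were named from the platform annotation by gene identifier, and comparison with the current rat gene table changed 0 symbols. Of the tested probe sets, 8120 had 1 gene, 245 had several and 1155 had none listed. Only those with 1 gene were named, and a gene was represented by its brightest probe set, which gave 7056 genes. The array names no genome build, so no coordinates are given.

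The 2 arrays of a pool are technical repeats of 1 RNA, so their mean log2 value was taken and the pool was the replicate (n = 10). Each diet level at each duration had 1 pool, so no condition had a repeated pool. The p-values therefore rest on how far pools depart from the fitted model. They do not measure the spread between rats or between pools of the same condition. The number of arrays limits the precision. Correlations between the arrays of a pool ran from 0.948 to 0.971, and those between arrays of different pools from 0.916 to 0.970. The closest other array was of the same pool for only 9 of the 20 arrays, and of another pool for the rest. The median SD between the arrays of a pool was 0.236 on the log2 scale, and 0.167 for a mean of 2 arrays from array spread alone. The median residual SD of pools, which are such means, around the dose trend was 0.207. The 2 arrays of a pool had the same value at 45 to 139 of 15923 probe sets, so neither was a copy of the other.

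Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean signal), two-sided, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The dose trend used percent restriction as a number with duration as a covariate, and slopes are given as the log2 change over 30 percentage points. Slopes for each duration and their difference came from 1 fit. Restricted pools were also set against control pools as a single step, and each level was set against control with level as a factor. Duration was tested with percent restriction as a covariate. Each restricted pool was compared with the control pool of its duration by a rule of size only, a log2 difference of at least 1 with both arrays of one pool above both of the other. The 34 gene lists were fixed before the data were examined, and the 27 with at least 3 measured genes were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and fry as checks.

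The genes named were set by a rule fixed before the data were examined. For the dose trend over both durations, the restriction step and the duration comparison, it took up to 12 largest rises and 12 largest falls past the threshold, with the same sign in both durations for the dose trend. For the separate slopes it took up to 5 in each direction, for their difference 3 in each direction by p, and for each level 3 in each direction. Up to 4 members of smallest p were taken from each list, and a fixed set of metabolic, hormonal, stress and clock genes was always included. Of that set, Sqle, Asns and Cdk1 lay under the signal filter.

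The scripts were tested on simulated pools in which 200 of 9520 probe sets were changed. For a dose trend of 2-fold, 69% were recovered with 8 false calls, and for 4-fold 100% with 11. For a restriction step of 2-fold, 84.5% were recovered with 14 false calls, and for the 30% level 50.5% with 5.

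Alternatives covered the scaling, the signal filter, an offset before log2, the variance model, the arrays as values with the pool as a random block, the scale of restriction, and fits without each array number or each pool. Fits added after seeing the data left out the dimmest array, raised low values, kept the restricted pools alone, or took the 3' over 5' signal ratio of GAPDH or of actin, a measure of RNA integrity, as a covariate.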

Results

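The liver of food-restricted rats was profiled in 10 pools of RNA, 1 for each of 5 diet levels at each of 2 durations. Each pool held RNA of 5 rats and was measured on 2 arrays, and 9520 probe sets for 7056 named genes were compared. The series title names mild food restriction as the question, and the levels ran from 0 to 30% at 1 week and at 1 month.

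Genes of fatty acid synthesis fell with increasing restriction over both durations. Fasn, the fatty acid synthase, fell by 3.87 ± 0.55 (SE, n = 10 pools) on the log2 scale over 30 percentage points, a 14.6-fold lower signal (limma adjusted p = 0.0061). Acly, which makes cytosolic acetyl-CoA, fell by 2.34 ± 0.382 (adjusted p = 0.0094), and Srebf1, which encodes a transcription factor of lipogenic genes, fell by 1.57 ± 0.214 (adjusted p = 0.00541). Pnpla3, a lipid droplet protein, fell by 6.35 ± 1.18 (adjusted p = 0.0156), with 5 of its pools under the lowest mean signal tested (18.4-fold in the fit with these raised to it). Scd fell by 1.03, Elovl5 by 1.36, Me1 by 1.27 and Pklr, the liver pyruvate kinase, by 1.11. Of 26 measured genes of fatty acid and triglyceride synthesis, 15 fell, 0 rose and 11 did not pass, and 18 fell when adjusted over the list alone. By the separate slopes 4 fell at 1 week and 0 at 1 month, and 19 and 15 when adjusted over the list alone. The list was lower as a set (camera adjusted p = 9.75e-18), and with an estimated correlation adjusted p = 0.164.

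Cholesterol synthesis genes were lower as well, with 7 of 20 measured members falling, 13 falling when adjusted over the list alone, and a camera adjusted p of 8.23e-11 (adjusted p = 0.164 with an estimated correlation). Pmvk, a kinase of the mevalonate pathway, fell by 1.99 ± 0.321 (adjusted p = 0.00887), Fdps by 1.61 ± 0.239 and Dhcr7 by 1.70 ± 0.427. Other large falls were in Gckr (by 1.93 ± 0.285, adjusted p = 0.0061), Cyp2c12 (by 2.48), Slc34a2 (by 2.49), Fabp5 (by 1.96) and Map4k4 (by 2.14). Msx1, Apobec1 and Sectm1b fell by 1.97, 1.88 and 1.85. With low pools raised, the falls of Slc34a2, Map4k4, Msx1, Apobec1 and Sectm1b were 4.04-fold, 2.38-fold, 1.89-fold, 2.27-fold and 2.87-fold. Igf1 fell by 0.35 ± 0.065 (adjusted p = 0.0145). Second probe sets of Map4k4 (-1.40, adjusted p = 0.124) and Igf1 (-0.33, adjusted p = 0.0867) did not pass.

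The largest rise was in Mt2A, a metallothionein, at 3.04 ± 0.703 on the log2 scale (8.24-fold, adjusted p = 0.036). Nat8 rose by 2.94 ± 0.591, Por, the electron donor of microsomal cytochromes P450, by 2.31 ± 0.498, Lama3 by 2.26 ± 0.486, Trim36 by 2.18 (2.37-fold with low pools raised) and the sulfotransferase Sult2a6 by 2.00 ± 0.299 (adjusted p = 0.0061). Inmt, Eif4ebp3, the serine dehydratase Sds, Mcrip2, Rhbdd2 and Hacl1 rose by 1.84, 1.71, 1.69, 1.43, 1.41 and 1.36. Of 45 drug-metabolising genes, 10 rose, 2 fell and 33 did not pass (camera adjusted p = 0.00271, and adjusted p = 0.164 with an estimated correlation), with Por, Sult2a6, Cyp2e1 and Nr1i3 among those that rose and Cyp2c12 and Cyp2a2 falling. Of 41 genes of fatty acid oxidation, 4 rose, among them Ehhadh and Eci1, and Crot and Plin2 fell (camera adjusted p = 0.000898, and adjusted p = 0.448 with an estimated correlation). Of 39 genes of amino acid breakdown and the urea cycle, 5 rose and 2 fell, with Sds, Kmo and Gpt among those that rose (camera adjusted p = 0.0103, and adjusted p = 0.164 with an estimated correlation).

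Endoplasmic reticulum chaperones were lower as a set, with 5 of 21 falling, Hspa5 by 0.57 ± 0.118, and Edem1 rising (camera adjusted p = 0.00108, and adjusted p = 0.164 with an estimated correlation). The interferon and antigen presentation list was lower, with Psmb8 and Psmb9, subunits of the immunoproteasome, the 2 of 21 members that fell (camera adjusted p = 0.000575, and adjusted p = 0.169 with an estimated correlation). Proteasome subunits (camera adjusted p = 0.000898, 1 of 27 falling) and cell cycle genes (camera adjusted p = 0.00561, 0 of 15 passing) were lower as sets, with adjusted p = 0.329 and adjusted p = 0.164 with an estimated correlation. Heat shock proteins (camera adjusted p = 0.0117) and the clock list (camera adjusted p = 0.0117) were higher with 0 members passing, with adjusted p = 0.164 and adjusted p = 0.329 with an estimated correlation. Endothelial markers were higher (1 of 7, Ehd3, camera adjusted p = 0.0103) and bile duct markers lower (0 of 3, camera adjusted p = 0.0148), each with adjusted p = 0.164 with an estimated correlation.

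Over all probe sets, 358 passed for the dose trend, 171 higher and 187 lower, against 18 higher and 40 lower with the signals as deposited. The 3' over 5' ratio of GAPDH, which is higher in less intact RNA, fell with restriction over the 10 pools, within 1.27 to 1.67. The ratio also differed between the 2 arrays of 1 RNA, at 1.42 and 1.14 for the 30% pool at 1 month. In other pools the arrays were closer, at 1.54 and 1.53 for the 10% pool at 1 week. Part of the range between pools may thus be array noise. For the pool means of GAPDH r was -0.69 (permutation p = 0.024, adjusted 0.033 over 2 ratios), and -0.61 without the 30% pools. Spearman's rho was -0.71 (permutation p = 0.0272, adjusted 0.0544). For actin r was -0.68 (permutation p = 0.033, adjusted 0.033; rho = -0.57, permutation p = 0.0989, adjusted 0.0989), and it was -0.17 without those pools. With the GAPDH ratio as a covariate 0 probe sets passed in limma and 1350 had an unadjusted p under 0.05, and with the actin ratio 8 passed. All 358 slopes kept their sign with the GAPDH ratio, at a median of 1.08 times their size, and Fasn fell by 3.99 ± 0.795, but the median standard error was 1.43 times as large and the lowest adjusted p was 0.0509. The single-gene calls over all probe sets thus depend on leaving these ratios out of the fit. The fatty acid synthesis list had a camera adjusted p of 1.84e-14 with the GAPDH ratio, and adjusted p = 0.247 with an estimated correlation. Without the 30% pool at 1 week 66 passed.

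**Figure D1:**
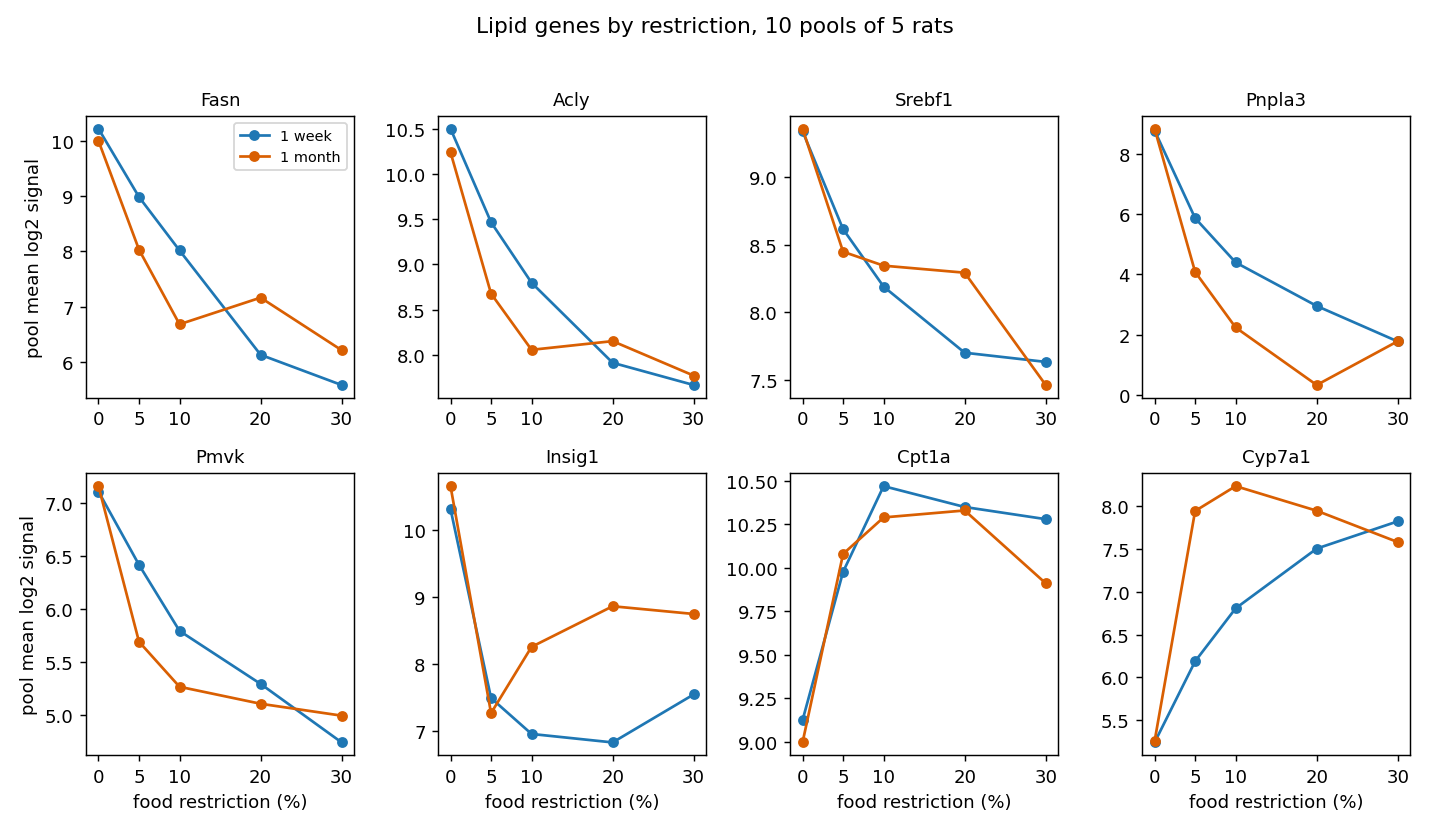
Pool mean log2 signal (vertical axis) of 8 lipid genes against food restriction in percent (horizontal axis), with 1 line per duration and 1 point per pool of 5 rats measured on 2 arrays. Fasn fell from 10.22 in the 1 week control pool to 5.58 at 30%, and Cpt1a and Cyp7a1 were higher in restricted pools.

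When all restricted pools were set against the control pools as a step, genes of the circadian clock separated them. Dbp, a clock-controlled transcription factor, rose by 4.98 ± 0.604 (SE, n = 10 pools, limma adjusted p = 0.00106), at least 14.8-fold because its control pools lay under the lowest mean signal tested. Per2 rose by 2.79 ± 0.286 (at least 4.88-fold, adjusted p = 0.000657), Nr1d2 by 2.06 ± 0.22, Usp2 by 2.04, Cry2 by 1.57 ± 0.14 and Hlf by 1.40. Clock fell by 0.94 (adjusted p = 0.0283), and passed with median centring but not with the signals as deposited (adjusted p = 0.0797). Bmal1 was lower by 2.23 ± 0.604 without passing (adjusted p = 0.0522), with 5 of its pools under that level, and Nr1d1 had a difference of 1.29 ± 0.565 (adjusted p = 0.239). Of 13 clock genes, 6 rose and 1 fell (camera adjusted p = 6.55e-06, and adjusted p = 0.144 with an estimated correlation).

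**Figure D2:**
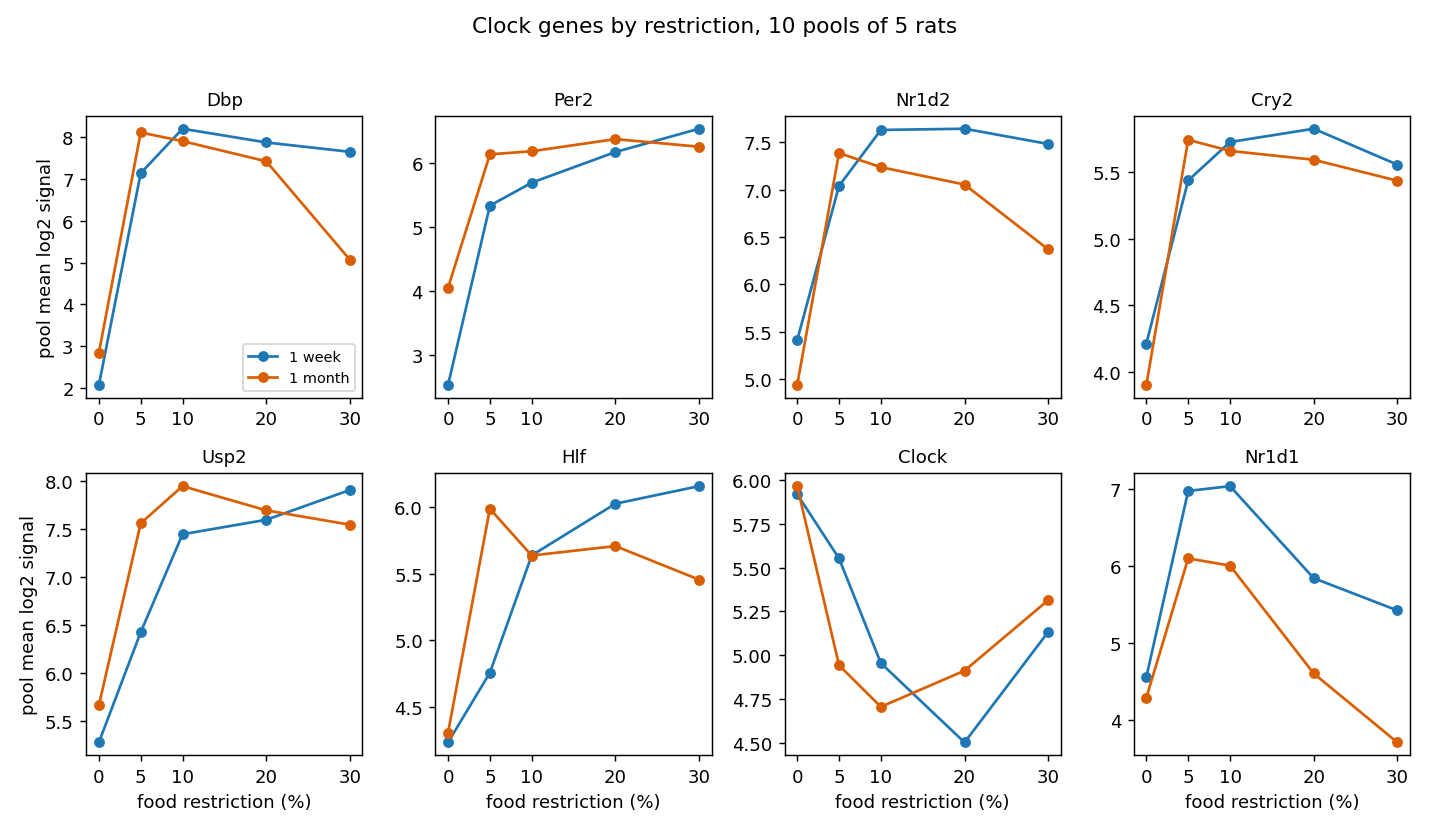
Pool mean log2 signal (vertical axis) of 8 clock genes against food restriction in percent (horizontal axis), with 1 line per duration and 1 point per pool of 5 rats measured on 2 arrays. Dbp was 2.06 and 2.83 in the control pools and between 5.07 and 8.21 in the restricted pools.

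Some genes of bile acid synthesis and of fatty acid oxidation rose in the step, with single genes of other functions. These differences rest on the same control pools as those of the clock genes, and no time of day at sampling is given for them. Hsd17b2, a steroid dehydrogenase, rose by 3.88 ± 0.321 (14.7-fold, adjusted p = 0.000112), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 2.26 ± 0.331 (4.79-fold, adjusted p = 0.00255). Abcg5, a sterol transporter, rose by 2.21 ± 0.307 (at least 4.57-fold), and Adh4 by 2.29 ± 0.325. Mt2A, Nat8 and Por rose by 3.15, 2.66 and 2.26, Bcar3 by 2.13 (at least 1.73-fold) and Pla2g12a by 2.12 (at least 2.27-fold). Of 20 genes of bile acid synthesis and transport, 6 rose and 0 fell (camera adjusted p = 0.000352, and adjusted p = 0.202 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, rose by 1.15 ± 0.122 (2.22-fold, adjusted p = 0.000723), Eci1 by 1.35 ± 0.16 and Ech1 by 1.64 ± 0.197, and 10 of 41 fatty acid oxidation genes rose while Pdk4 fell by 0.93 ± 0.243 (camera adjusted p = 1.15e-08, and adjusted p = 0.144 with an estimated correlation). Cyp4a1 was higher by 0.58 ± 0.161 without passing (adjusted p = 0.0578).

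In the step Pnpla3 fell by 5.89 ± 0.954 (at least 27.9-fold). Other falls were in the taurine transporter Slc6a6 (by 3.81 ± 0.471, at least 12.8-fold), Tubb2a (by 3.23), Insig1, a sterol-regulated protein (by 2.74 ± 0.335, 6.68-fold, adjusted p = 0.00106), Cdkn1a (by 2.73, at least 5.69-fold), Chka (by 1.80) and Dhcr7 (by 1.80). Fasn, Acly, Cyp2c12, Pmvk and Fabp5 fell by 3.01, 2.06, 1.99, 1.72 and 1.71. In fatty acid synthesis 14 of 26 fell and Dgat2 rose (camera adjusted p = 5.17e-15, and adjusted p = 0.146 with an estimated correlation), and in cholesterol synthesis 9 of 20 fell (camera adjusted p = 5.48e-13, and adjusted p = 0.144 with an estimated correlation). Also lower as sets were proteasome subunits (camera adjusted p = 1.74e-05, and adjusted p = 0.146 with an estimated correlation), ribosomal proteins (camera adjusted p = 6.62e-05, and adjusted p = 0.398), cell cycle genes (camera adjusted p = 0.00165, and adjusted p = 0.187) and endoplasmic reticulum chaperones (camera adjusted p = 0.00184, and adjusted p = 0.202). Drug-metabolising genes were higher (camera adjusted p = 0.0195, and adjusted p = 0.398 with an estimated correlation). In all 502 probe sets passed, 301 higher and 201 lower, against 295 and 46 with the signals as deposited. With the GAPDH ratio as a covariate 424 passed, and without the 1 month control pool 62 passed.

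At 5% restriction against control 43 probe sets passed, 26 higher and 17 lower. Dbp was higher by 5.19 ± 0.644 (at least 17.0-fold), Hsd17b2 by 4.06 ± 0.353 and Mt2A by 2.52 ± 0.448, and Pnpla3, Insig1 and Slc6a6 fell by 3.84, 3.10 and 3.03. At 10% the count was 208 (127 higher), at 20% 362 (206 higher) and at 30% 431 (233 higher). Fasn fell by 4.21 ± 0.461 at 30%, and Nat8 rose by 3.35 ± 0.485 there. At 10% Cdkn1a fell by 3.28 ± 0.587 (at least 6.08-fold), and at 20% Tubb2a fell by 3.83 ± 0.692. Each level had 2 pools, and without the 1 month pool at 5% only 2 probe sets passed for that level. At 30% 204 passed with the GAPDH ratio and 1 with the actin ratio as a covariate, and without a variance trend 0 passed at 5, 10 and 20% and 107 at 30%.

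The signals as deposited gave 85 higher and 27 lower at 5%, 342 and 29 at 10%, and 579 and 51 at 20%, and median centring gave 11 and 16 at 5%. The level effects share the same 2 control pools. Between 5% and 30% they correlated at r = 0.68 across probe sets, which are not independent replicates, against 0.50 in simulated unchanged pools, with a covariance of 0.114 against 0.0370. They shared 20 higher and 13 lower calls, against 0.636 and 0.354 for independent lists. The simulated pools shared 0 calls, which decides little, since unchanged pools hold no changed genes to share. Part of the excess over independent lists may come from the shared controls, which could not be split. Between pools of different durations, which share no control, differences from control correlated at 0.05 to 0.13 between the 5% pool at 1 week and each 1 month pool, and at 0.30 to 0.46 for the other pools. By the rule of size, 360 probe sets separated the 5% pool from its control at 1 week and 559 separated the 30% pool, and at 1 month 535 and 472 did.

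At 1 week 68 probe sets passed for the dose slope, 28 higher and 40 lower, against 10 and 33 with the signals as deposited and 20 and 52 with median centring. Hamp, the iron regulatory hormone hepcidin, fell by 3.66 ± 0.464 (12.7-fold, limma adjusted p = 0.0202), Fasn fell by 4.70 ± 0.733, Fam171a1 fell by 3.13, Mvd by 2.99 and the cyclin Ccnb1 by 2.91 (2.20-fold, 2.11-fold and 2.57-fold with low pools raised). Inmt, Trim36, Snrk, Eif4ebp3 and Gas5 rose by 2.70, 2.95, 2.14, 2.03 and 1.58, with Trim36 at 2.55-fold and Snrk at 2.99-fold with low pools raised. At 1 month 3 probe sets passed and 995 had an unadjusted p under 0.05, among them Hes6, which fell by 1.14 ± 0.147, and Abcc2, a canalicular export pump, which fell by 1.03 ± 0.132 (both adjusted p = 0.0292). With the GAPDH ratio as a covariate 1 passed at 1 week and 0 at 1 month, and without the 1 week control pool or without a variance trend 0 passed at 1 week. Of the 3 at 1 month, 0 passed with the signals as deposited, where 3 others did, and 0 without a variance trend.

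The difference between the slopes was past the threshold for 0 probe sets in limma, with 525 at an unadjusted p under 0.05 and 476 expected by chance. Smallest p belonged to Hamp (difference 3.81 ± 0.656, adjusted p = 0.611) and Nono (-1.20 ± 0.208, adjusted p = 0.611), which did not pass. As a set, the amino acid response list had a lower slope at 1 month, with a median difference of -0.72 over 15 genes and 0 passing singly (camera adjusted p = 1.19e-05, and adjusted p = 0.122 with an estimated correlation). Its median rose to 0.61 at 30% at 1 week and was -0.20 at 30% at 1 month.

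**Figure D3:**
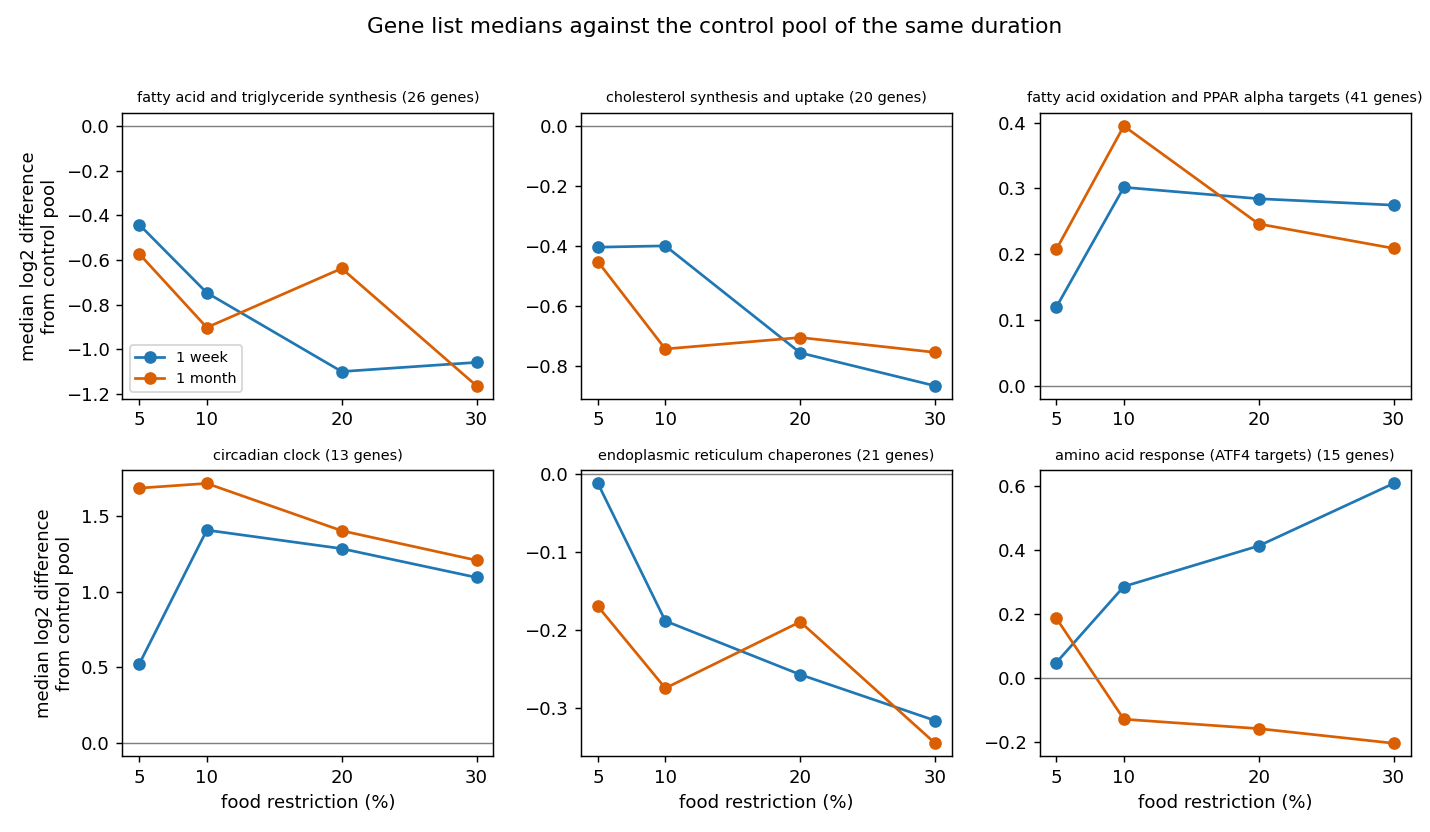
Median log2 difference from the control pool of the same duration (vertical axis) over the measured genes of 6 fixed lists, against food restriction in percent (horizontal axis), with 1 line per duration and 1 point per pool. The fatty acid synthesis median was -1.06 at 30% at 1 week and -1.16 at 1 month.

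Between durations, 32 probe sets passed for 1 month against 1 week, 16 higher and 16 lower, and changes were small. Cdh17, a cadherin, rose by 0.94 ± 0.157 (1.92-fold, limma adjusted p = 0.033), Cyp3a9 by 0.89 ± 0.133, Vamp7 by 0.76 and Gpt, an alanine aminotransferase, by 0.70 ± 0.0921. Dnase2b, Aspg, Xpnpep2, Mrpl34, Orm1 and Obp3 rose by 0.72, 0.69, 0.58, 0.47, 0.43 and 0.43. Abcc2 fell by 0.68 ± 0.0855 (adjusted p = 0.0108), Msmo1, of sterol synthesis, by 0.65, Col3a1, a fibrillar collagen, by 0.63 ± 0.0696 (adjusted p = 0.00863), Hbb, a globin of red blood cells, by 0.57, Echdc1 by 0.57 and Nrep by 0.53. Genes of amino acid breakdown were higher as a set (1 of 39, Gpt, and 11 when adjusted over the list alone, camera adjusted p = 1.41e-06, and adjusted p = 0.00995 with an estimated correlation). Endoplasmic reticulum chaperones (camera adjusted p = 0.000238, and adjusted p = 0.206 with an estimated correlation), stellate cell and fibroblast markers (1 of 14, camera adjusted p = 0.00124, and adjusted p = 0.0721) and cholesterol synthesis (camera adjusted p = 0.0263, and adjusted p = 0.637) were lower, and oxidative phosphorylation was higher (camera adjusted p = 0.000322, and adjusted p = 0.521). Duration, age and any processing batch changed together and cannot be told apart. The signals as deposited gave 3 higher and 0 lower, median centring 5 and 8, the arrays numbered 1 alone gave 5 in all, and the fit without a variance trend gave 1.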

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

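The test of scaling for the amino acid response list was chosen after its result was seen, and the fits that left out 1 pool before. 4 gene lists differed in dose slope between the durations by the camera test of the difference itself, and 0 of them did so with an estimated correlation. Targets of the amino acid response had the largest difference, with a median of -0.72 on the log2 scale over 30 percentage points (adjusted p = 1.19e-05, and adjusted p = 0.122 with an estimated correlation). Slc3a2, an amino acid transporter subunit, rose by 1.25 ± 0.244 over the dose range at 1 week (limma adjusted p = 0.0474) and had a slope of 0.14 ± 0.244 at 1 month. The tables argue against 1 pool alone, since the highest adjusted p over the fits that each left out 1 pool was 0.000483, and against the scaling of the arrays, since the list median was -0.74 with the signals as deposited and nothing subtracted. Correlation between the genes stays open, as does a difference in age or processing batch, because each duration was 1 set of pools.

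Bile acid synthesis and transport had a lower slope at 1 month (median difference -0.29, camera adjusted p = 0.0264, and adjusted p = 0.838 with an estimated correlation). Cholesterol synthesis had a higher one (median difference 0.32, camera adjusted p = 0.0405, and adjusted p = 0.838 with an estimated correlation). Oxidative phosphorylation had a higher one as well (median difference 0.09, camera adjusted p = 0.0406, and adjusted p = 0.838 with an estimated correlation). Over the 10 fits that each left out 1 pool, these calls were lost in 4, 6 and 7 fits, with highest adjusted p of 0.923, 0.968 and 0.325, and oxidative phosphorylation was also lost with the signals as deposited (adjusted p = 0.703) and with median centring (adjusted p = 0.0557).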

How the results depend on the processing

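Fits with the 3' over 5' ratios, with restricted pools alone, with low values raised, without the dimmest array and with the signals as deposited were chosen after seeing the data, and the actin fit only after the GAPDH fit. Named gene effects changed sign in 0 cases where either fit passed. Where neither passed, the sign changed for up to 6 values, with the restricted pools alone. Calls were often lost, and the 145 values include genes that did not pass as reported. The calls lost were 82 without a variance trend, 62 with the actin ratio and 57 with the GAPDH ratio. They were 34 with the arrays numbered 1 alone, 33 with the signals as deposited and 24 of 43 values with the restricted pools alone. Fits that left out 1 pool lost calls as well. In the order dose trend, 1 week slope, 1 month slope, step, 5, 10, 20 and 30% level and duration, the fit without a variance trend called 108, 0, 0, 192, 0, 0, 0, 107 and 1 probe sets. The signals as deposited gave 58 for the dose trend, 43 at 1 week, 1 for the slope difference, 112, 371, 630 and 261 for the levels, 3 for duration and 8 lists at 1 week, and had a median over all probe sets of 0.25 in the step and 0.41 at 20%, against 0.00 and 0.01 as reported. Median centring gave 6 at 1 month, 27 at 5%, 13 for duration and 9 lists for duration. No filter gave 32 at 1 week and 17 for duration, and raised low values gave 5 at 1 month. Without the dimmest array 22 passed at 5% and 6 for the 1 month slope. Ranks of the levels gave 626, 250 and 21 for the dose trend and both slopes, and the restricted pools alone gave 46.

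With the GAPDH ratio in the fit, 0, 1 and 0 passed for the dose trend and both slopes, 14, 213 and 204 at 5, 20 and 30%, and 17 for duration. With the actin ratio, 8, 0 and 0 passed, then 2, 116, 204 and 1 at the levels and 20 for duration. The dose trend calls ended because the ratio moved with restriction (partial correlation -0.69) and widened the standard errors. Among 100 covariates of noise with that correlation, the median count was 5, 28 gave 0 and the highest was 910. For the other settings the cause was not tested.

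Arrays of the same number did not deviate together over all probe sets: the correlation of array differences between pools was over 0.1 in 2 of 45 pairs of pools. The dap control signal did, and was higher on the array numbered 1 in 10 of 10 pools. With all 20 arrays, the pool as a random block and the array number as a block, 818, 553 and 157 passed for the dose trend and slopes, 2 for their difference, 884 for the step, 276, 674, 885 and 1002 for the levels and 197 for duration. Without the array number these were 829, 597, 165, 1, 915, 286, 684, 896, 1005 and 194.

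Leaving out a pool or an array number, counts ran from 66 (without 1 week 30%) to 469 for the dose trend, from 0 (without the 1 week control) to 418 (without the 1 month control) at 1 week, from 0 to 6 at 1 month and from 0 to 11 for the slope difference. They ran from 62 (without the 1 month control) to 888 (without 1 week 5%) for the step, from 2 to 156 at 5%, 18 to 366 at 10%, 22 to 472 at 20%, 107 to 565 at 30%, and 5 to 34 for duration. A level or control left with 1 pool was assumed to vary like the others. List counts ran from 12 to 16 for the dose trend, 9 to 16 at 1 week, 4 to 11 at 1 month, 1 to 11 for the slope difference, 6 to 11 for the step and 5 to 9 for duration. With an estimated correlation 0 lists passed in any of these, except 1 for duration. The fry check was run on the reported fits and was not adjusted over the lists, so it gave no calls. By fry, the lists called by camera for the dose trend were under 0.05, except fatty acid oxidation and the clock. In the step all called lists were. At 1 week and at 1 month several were not, among them fatty acid oxidation. For the slope difference only the amino acid response was, and for duration all but cholesterol synthesis. Single pool differences, 3756 in all, became 15200 with no filter, 1506 in the upper 40%, 11263 with a 1.5-fold rule and 2407 with the offset. Signals near background limit the folds of Pnpla3 and Dbp in the step to lower bounds.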

Other observations

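The tests on the opposite clock phase, on the scaling of the fatty acid list, on grading among the restricted pools and on the single-gene calls and slopes with the GAPDH ratio were chosen after their results were seen. Among the 8 restricted pools alone, 46 probe sets changed with percent restriction, including genes that did not pass in the step. Nr1d1, a clock repressor, fell by 2.16 ± 0.218 over 25 percentage points (limma adjusted p = 0.00318), and Igfbp1, an insulin-repressed binding protein, rose by 1.87 ± 0.197 (adjusted p = 0.00327). Against control, Nr1d1 was higher by 2.11 ± 0.28 at 5% (adjusted p = 0.0161) and by 0.14 ± 0.28 at 30% (adjusted p = 0.851), and Igfbp1 differed by -1.22 ± 0.213 at 5% (adjusted p = 0.0491) and by 0.74 ± 0.213 at 30% (adjusted p = 0.0839). Elovl5, Srebf1, Fasn and Acly fell by 0.97, 0.94, 2.42 and 1.25.

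Several genes, and several lists as sets, showed no shift past a threshold. Pck1, Cyp2c11 and A2m had slopes of 0.10 ± 0.0907, -0.07 ± 0.0611 and 0.00 ± 0.288, and Fgf21 of -0.56 ± 0.409. For the dose trend, gluconeogenesis (camera adjusted p = 0.0978), glycolysis (camera adjusted p = 0.213), acute phase and complement proteins (camera adjusted p = 0.829), lipoprotein assembly (camera adjusted p = 0.829) and hepatocyte markers (camera adjusted p = 0.975) did not pass as sets. Single members did pass. In gluconeogenesis Sds and Gpt rose and Pygl fell, and in glycolysis Pklr and Ldha fell. C9 fell among acute phase and complement proteins, and Cyp2e1 rose among hepatocyte markers. In lipoprotein assembly 0 of 15 genes passed.

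Of 13 clock genes, 6 or 7 passed at each level against control, not the same ones at each, and the list did not pass with an estimated correlation (lowest adjusted p = 0.189 over the levels). Scaling of the arrays is argued against, since 6 of the 7 called members kept sign and call under both other scalings. For a single odd control pool, the median size of the called members' difference was 2.02 in the duration with the smaller one. This decides little, since members were called in a fit over both control pools. Over all 13 measured genes the median difference from control was 0.52 to 1.41 at 1 week and 1.21 to 1.71 at 1 month. The list was thus higher in both durations. Bmal1 and Clock, of the opposite phase to Dbp and Per2, had a median difference of -1.58, which decides little, since these are 2 genes and 5 pools of Bmal1 lay under the lowest mean signal tested. Whether diet shifted the clock, or control rats were sampled at another time of day or fed on another schedule, cannot be told apart because no time of day is given in the labels used here. The same limit holds for other genes set against these control pools, in the step, the levels and the dose trends. The step gave 502 probe sets. Of the 25 choices of a control pool per duration only the real one gave as many, and the highest of the others gave 9. The count is thus unlikely by chance, but 25 choices are too few to exclude it.

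The fatty acid synthesis genes were lower with restriction. Among the restricted pools alone the list had a camera adjusted p of 5.47e-12 at the preset correlation, but adjusted p = 0.281 with an estimated one. A step with no grading is therefore not decided. The list median differences from control at 5, 10, 20 and 30% were -0.44, -0.75, -1.10 and -1.06 at 1 week. At 1 month they were -0.57, -0.90, -0.64 and -1.16. Scaling is argued against by a list median slope of -0.85 with the signals as deposited and nothing subtracted, where the median of all probe sets was 0.11. With the GAPDH ratio in the fit the list median slope was -0.93. This argues against RNA quality, as far as this ratio measures it, as the whole cause for the list. Of the 15 called members, 14 passed with the ratio when adjusted over the list alone, with slopes at a median of 1.005 times their size. These members were picked by the same slope in the same pools and so decide little. The list was not fitted with the actin ratio. Another sampling time or feeding schedule of the control rats was not tested for the list. Over all probe sets 0 calls remained with that covariate, because the standard errors widened and not because slopes shrank (Fasn fell by 3.87 ± 0.55 before and fell by 3.99 ± 0.795 after). By the count of calls alone RNA quality and restriction cannot be told apart, since the ratio moved with restriction. The fall of the list is left as a hypothesis that may be biological, and it did not pass with an estimated correlation, with the ratio (adjusted p = 0.247) or without it (adjusted p = 0.164). The dose trend gave 358 probe sets. Of 100 orderings of the levels only the real one gave as many, and the highest other gave 221. The count is thus unlikely by chance, which 100 orderings cannot exclude.

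For duration, 3 of 100 splits of the pools into 5 and 5 gave 32 or more probe sets, the real one included, and the highest other gave 74. That share is under 0.05 for the count as reported. However, 2 other splits gave more, 74 and 43, and the count was 5 with the arrays numbered 1 alone and 1 without a variance trend. Chance is therefore not excluded for duration.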
